A study of Mus musculus with 2 samples.

How the data were processed

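Total RNA was measured in the left cerebral cortex of 2 male mice on postnatal day 4. The mice were F1 hybrids of the C57BL/6 and CAST strains, and each gave 1 library. Per the labels, 300 ng of RNA went into each library, ribosomal RNA was reduced, the libraries kept strand, and ERCC spike-in RNAs were added. The replicate numbers come from the labels, which list separate tissue samples for the 2 libraries. No other group was sampled, so there is no contrast between conditions, and paired designs and other splits of the samples do not arise.

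The authors deposited 1 gene table and 2 transcript tables per library. Per the file headers, the gene table and 1 transcript table hold expected counts, TPM and FPKM, together with posterior mean TPM and the bounds of a TPM interval. The transcript table of this kind also gives, per the file headers, each transcript's percent of its gene. The other transcript table holds estimated counts and TPM, per the file headers. These tables are called the alignment-based quantification and the other quantification below. The deposited notes name the mm10 assembly and the GENCODE M21 annotation. The aligner, the quantifiers, their versions and whether counting used strand are not given in the sources used here. Alleles were not told apart. Values were set against mm10, and whether transcripts of the CAST allele were counted in full was not tested here, which bears on every level. The deposited FPKM values entered no result.

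All 55536 annotated gene identifiers of the gene table matched the M21 annotation, which gave symbols, classes and mm10 coordinates. The gene table also held 97 spike-in rows, phiX among them, and 26248 rows with a numeric identifier that the tables pair with no name. Both kinds stayed out of library sizes and tests. Spike-in rows took 0.323% of the expected counts in replicate 1 and 0.351% in replicate 2, and the numeric rows took 6 and 2 reads. Libraries held 26897687 and 29511737 expected counts, these rows included. A gene with 0 reads may have a true level of up to 3 counts, which is 0.112 CPM in replicate 1 and 0.102 CPM in replicate 2. Intervals and such limits cover counting error only, since reads carried no molecular identifiers that are named in the sources used here.

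A gene was called detected at a TPM of 1 or more in each library. Levels are means ± SD over the 2 libraries. Correlations across genes used log2(TPM + 1) for genes with a TPM of 1 or more in either library. Ratios are replicate 2 over replicate 1, from expected counts scaled with TMM factors of edgeR 4.0.16 in R 4.3.3, with a prior count of 0.5. The standard error of such a ratio comes from the counts alone. A two-sided exact binomial test per gene was run on rounded expected counts, with Benjamini-Hochberg adjustment over the genes with 10 or more counts in total and a threshold of 0.05. It compares these 2 libraries and says nothing about conditions. The biological coefficient of variation is the square root of edgeR's common dispersion with an intercept-only design after filterByExpr. A chi-square test over the genes of the binomial test asked whether the libraries agree within sampling noise. An exact sign test across 2 animals cannot give a p below 0.5, and no other test across the 2 animals was run, so levels and pairs carry no p-value.

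The 36 gene lists, the 14 gene pairs and the rule for named genes were fixed before the data were examined. The rule takes the 15 annotated genes with the highest mean TPM. It takes up to 4 of the highest members and the lowest detected member of each list, and every pair gene. It takes the 10 largest and the 10 smallest ratios among genes with at least 200 counts in both libraries together and an adjusted p under 0.05. It also takes the sex chromosome genes and 14 genes with known isoforms. Genes named outside it are members of the lists, of the gene families or of the olfactory bulb markers, or genes with reads almost only in 1 library, and they were chosen after their values were seen. A list's level is the median TPM of its detected members, set against 10000 random lists of detected protein-coding genes of equal size. A list's ratio is the median over members with at least 10 counts in each library, set against 10000 random lists matched in 20 bins of expression. A list stands apart in the lowest or highest 0.5% of these. Spread over genes is the scaled median absolute deviation. A pair ratio is log2 of TPM + 0.1 of the first gene over the second, and a pair was called when both libraries had the same sign and the mean exceeded 2 SD. Transcript pairs set a gene's highest transcript against its highest other protein-coding transcript whose coding length was within 80% of it either way. That bound, and the genes shown this way out of 14 candidates, were chosen after their values were seen. Shares of genes carry Wilson 95% intervals.

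The tests were tried on simulated data with known answers. The binomial test of 2 libraries was run on 20050 genes, of which 200 with 100 or more reads in total were changed. All of the genes changed by 4-fold, 97.5% of those changed by 2-fold, 64.2% of those changed by 1.5-fold and 60.4% of those changed by less were called. Genes with fewer reads were not changed, so these rates do not cover them. Of 19850 unchanged genes 6 were called. The list test was run on 20365 genes with 12 members per list, all members with 100 or more reads in total. There 1 of 200 lists without a shift and 50 of 50 lists with a shift of 0.5 stood apart. Those counts varied by sampling alone and independently between genes, so genes that vary together between animals were not simulated. For the dispersion, run on the filtered genes, a simulated coefficient of 0.1 came back as 0.0991.

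The alternatives were other thresholds and pseudocounts, median-ratio size factors as DESeq2 defines them (computed with edgeR's RLE method) and total count scaling, other count filters, the median of DESeq2 1.42.0's dispersion trend, the other quantification, and each library on its own. Other software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Symbols Ctgf and Scn2a1 were taken under their present names Ccn2 and Scn2a. Some single genes are not reported here, which leaves 13 gene pairs and 5 transcript pairs described; counts and medians of lists and pairs include all members.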

Results

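The data describe which genes and transcripts the left cerebral cortex of the newborn mouse expressed, and how far 2 animals differed. Both animals were males on postnatal day 4 from a cross of the C57BL/6 and CAST strains, and each gave 1 total RNA library. Ribosomal RNA had been reduced and ERCC spike-ins, a set of synthetic RNAs of known amount, had been added. The libraries held 26897687 expected counts in replicate 1 and 29511737 in replicate 2. Levels are TPM, a unit that sets a gene's transcripts against all transcripts of the library, as mean ± SD over the 2 animals (n = 2). Coordinates are those of mm10. A total of 15577 of 55536 annotated genes (28.0%) reached a TPM of 1 in both libraries, among them 13084 of 22028 protein-coding genes (59.4%) and 305 of 5854 lincRNA genes.

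Short structural RNAs and mitochondrial RNAs held the highest levels, and Tuba1a, which encodes an alpha-tubulin of growing neurons, held the highest level of any nuclear protein-coding gene. Tuba1a (ENSMUSG00000072235.6, 15:98949837–98953703) stood at 4325 ± 63.4 TPM. The 7SL genes Rn7s1 and Rn7s2, which encode the RNA of the signal recognition particle, were each listed at 117821 ± 6383 TPM. Rn7sk, an RNA that holds back transcription elongation, stood at 48393 ± 345 TPM, and Rpph1, the RNA of ribonuclease P, at 7789 ± 415 TPM. The mitochondrial ribosomal RNAs mt-Rnr2 and mt-Rnr1 reached 26498 ± 1409 and 17239 ± 1212 TPM, and mt-Co1, a subunit of cytochrome oxidase, 3991 ± 173 TPM. The other 7 genes of the 15 highest are uncertain, because their reads can be shared with copies or with ribosomal RNA. They were Gm26917 (20711 ± 464 TPM) and Gm42418 (3677 ± 106) on chromosome 17, the chromosome 1 pseudogenes Gm28661 (5083 ± 145), Gm10925 (4303 ± 65.0) and Gm28437 (3632 ± 336), and the snRNA genes Gm23444 and Gm23472 (3641 ± 577 each). Rn7s1 and Rn7s2 had equal values and are uncertain for the same reason, as are Rn7sk and Rpph1, which share 72.8% and 70.2% of their 31-base words with other genes.

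Protein-coding genes outside the ribosomal protein, histone and mitochondrial classes took 48.2 ± 0.559% of the TPM and 82.2 ± 0.00594% of the expected counts. Small structural RNAs took 34.1 ± 1.11% of the TPM but 4.16 ± 0.247% of the counts, since TPM divides by transcript length. Mitochondrial ribosomal RNA took 4.37 ± 0.262% of the TPM, long noncoding genes 4.29 ± 0.190%, ribosomal protein genes 2.56 ± 0.0151% and histone genes 0.352 ± 0.0232%.

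Genes of immature, growing neurons stood at the highest level of the neuronal lists. The 15 genes for immature neurons and axon growth had a median of 775 ± 10.7 TPM, against 17.62 TPM for the 13084 detected protein-coding genes. Tubb2b (1985 ± 8.21 TPM), Stmn1 (1765 ± 41.0), Tmsb10 (1428 ± 32.7) and Tubb3 (1248 ± 45.9), which encode tubulins and regulators of microtubules and actin, led the list, and Igfbpl1 was lowest at 20.3 ± 3.66. The 16 synapse genes had a median of 172 ± 2.72 TPM. Syp, a synaptic vesicle protein, stood at 318 ± 44.7, the kinase subunit Camk2b at 305 ± 2.35, Vamp2 of the fusion machinery at 303 ± 19.1 and the scaffold Bsn at 34.8 ± 0.516. Both medians, and that of the excitatory neuron list, lay in the top 0.5% of random lists.

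The 12 excitatory neuron genes had a median of 70.4 ± 8.998 TPM. Nrgn, a calmodulin-binding protein, led with 310 ± 2.92 TPM, then the vesicular glutamate transporter Slc17a7 (146 ± 18.2) and the transcription factor Neurod6 (111 ± 18.7), with Neurod1 lowest at 12.8 ± 0.226. Upper layer genes had a median of 52.0 ± 2.56 TPM, led by Cux2 (106 ± 19.3), Plxnd1 (95.7 ± 7.05), Cux1 (85.4 ± 1.32) and Lhx2 (58.2 ± 8.12), and Unc5d was lowest at 20.8 ± 1.63. Deep layer genes had a median of 31 ± 1.68 TPM, led by Sox5 (75.2 ± 10.6), Bcl11b (65.1 ± 1.92), Tbr1 (62.5 ± 4.44) and Ldb2 (56.4 ± 4.93), with Zfpm2 at 10.1 ± 0.940. Interneuron genes had a median of 26.0 ± 5.55 TPM over 15 of 16 members. The peptide genes Sst (133 ± 11.3) and Npy (87.7 ± 7.71) and the GABA-synthesising enzyme Gad1 (68.6 ± 20.8) led, with Erbb4 at 37.8 ± 0.0141 and Vip at 2.13 ± 0.297. Pvalb, a marker of a later maturing interneuron class, had 3 and 5 reads. In the Cajal-Retzius list Reln, the secreted guidance protein, stood at 93.6 ± 7.37 TPM, Calb2 at 21.4 ± 12.03, Cacna2d2 at 16.8 ± 1.22 and Ebf3 at 1.20 ± 0.240, and 2 of 8 members were under 1.

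**Figure D1:**
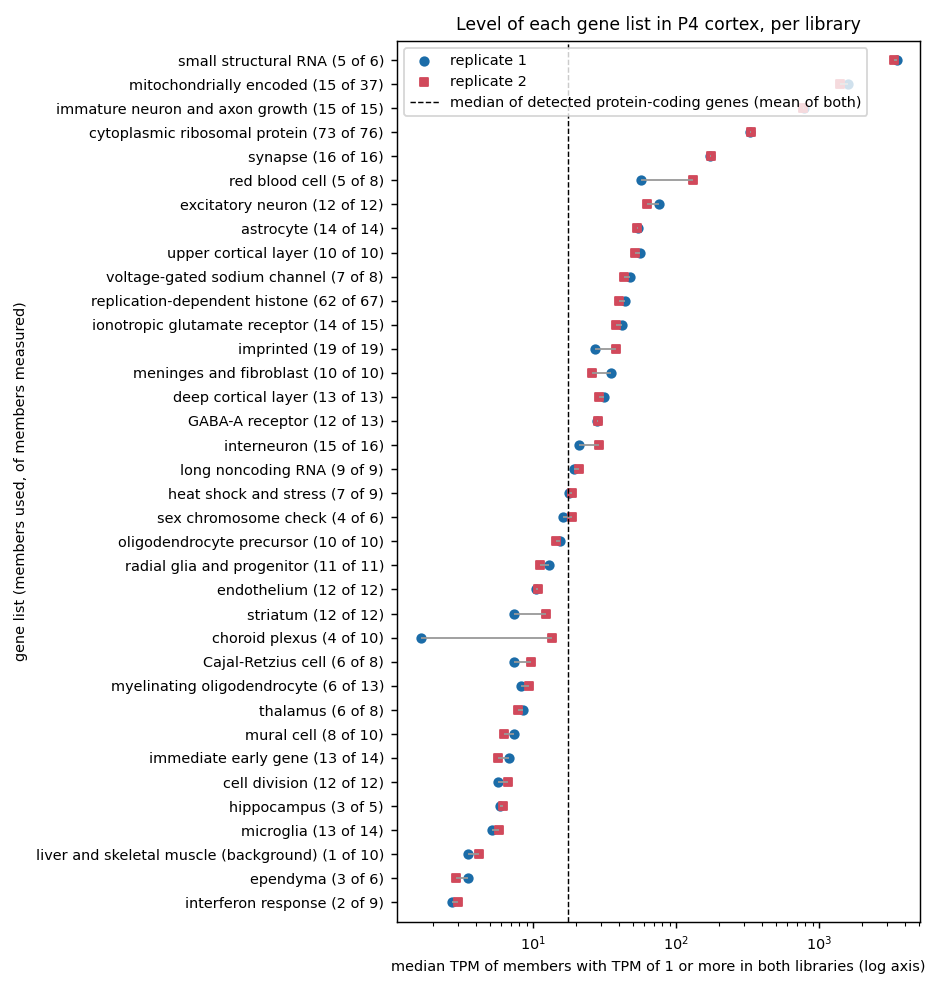
Median TPM (log axis) of the members of each gene list that reached a TPM of 1 in both libraries, with 1 point per library and a dashed line at the median of detected protein-coding genes (17.62 TPM). The list for immature neurons and axon growth stands at 775 TPM and the microglia list at 5.99 TPM.

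Astrocyte genes stood high among the glial lists, and no list, by its detected members, lay in the lowest 0.5% of random lists. Leaving out members under a TPM of 1 raises such medians. Over all members, the Cajal-Retzius, myelinating oligodendrocyte, choroid plexus, ependyma and mural cell lists lay there. So did the hippocampus, interferon response, mitochondrially encoded and liver and skeletal muscle lists. The random lists held detected genes only. The 14 astrocyte genes had a median of 53.8 ± 0.668 TPM, in the top 0.5% of random lists. The lipid carrier Apoe stood at 309 ± 30.4 TPM, Sparcl1 at 241 ± 11.7, glutamine synthetase Glul at 177 ± 3.18, the glutamate transporter Slc1a3 at 107 ± 4.55 and S100b at 3.23 ± 0.735. Oligodendrocyte precursor genes had a median of 14.9 ± 0.693 TPM, led by Ptprz1 (162 ± 4.04), Vcan (69.1 ± 10.9), Olig1 (45.9 ± 7.18) and the receptor Pdgfra (33.1 ± 3.29), with C1ql1 at 5.77 ± 0.792. Only 6 of 13 myelinating oligodendrocyte genes were detected. Mbp, a main protein of myelin, was at 19.5 ± 0.0707 TPM, Cnp at 14.4 ± 2.35, Cldn11 at 7.17 ± 2.10 and Mag at 1.44 ± 0.368. The microglia list had a median of 5.99 ± 0.403 TPM over 13 of 14 genes, with Csf1r at 10.02 ± 1.26, C1qb at 7.48 ± 0.255 and Siglech at 1.09 ± 0.0990.

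Progenitor and dividing cell genes were present at low to moderate levels. Radial glia genes had a median of 12.04 ± 1.18 TPM, with the fatty acid binding protein Fabp7 at 528 ± 11.5, Vim at 72.3 ± 6.77, Hes5 at 30.7 ± 3.27 and Eomes at 3.90 ± 3.23. Cell division genes had a median of 6.15 ± 0.682 TPM, from Pcna at 39.9 ± 1.09 and Top2a at 12.6 ± 2.20 down to Bub1 at 2.21 ± 0.742. Endothelial genes had a median of 10.7 ± 0.173 TPM, with the tight junction gene Cldn5 at 44.2 ± 6.07, and mural cell genes 6.65 ± 0.7495 over 8 of 10 (3.99 over all 10), with Rgs5 at 37.0 ± 2.06 and Vtn at 30.7 ± 0.962. Meningeal and fibroblast genes had a median of 31.3 ± 6.56 TPM, led by Ptgds (334 ± 2.83), Igf2 (159 ± 23.3) and Igfbp2 (75.4 ± 5.06), with Lum at 2.24 ± 0.509. In the choroid plexus list 4 of 10 genes were detected, among them Enpp2 (24.7 ± 0.955) and Ttr (16.7 ± 22.2), and in the ependyma list 3 of 6, with Foxj1 at 4.00 ± 0.919. Red blood cell genes had a median of 93.6 ± 51.8 TPM over 5 of 8 members, and 8.73 TPM over all 8, with the globins Hbb-bs at 113 ± 64.2, Hba-a1 at 111 ± 45.8 and Hba-a2 at 93.6 ± 51.8.

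Lists for neighbouring regions and for other tissues had medians under the 17.62 TPM of detected protein-coding genes. Striatal genes had a median of 10.3 ± 3.46 TPM, with Ppp1r1b, a regulator of dopamine signalling, at 38.0 ± 16.7 and Rgs9 at 20.4 ± 2.14. The hippocampus list had a median of 6.0 ± 0.255 TPM over 3 of 5 genes (2.13 over all 5), and the thalamus list 8.13 ± 0.467 over 6 of 8, with Slc17a6 at 22.4 ± 0.643 and Prkcd at 18.7 ± 2.76. Of the 10 liver and skeletal muscle genes, Acta1 alone was detected, at 3.85 ± 0.445 TPM. The Y-linked genes Eif2s3y (46.8 ± 0.318 TPM), Ddx3y (23.995 ± 2.54), Uty (10.975 ± 1.05) and Kdm5d (10.3 ± 1.11) were expressed, while Xist, the RNA of the inactive X chromosome, had 15 and 7 reads. Tsix, its antisense partner, was at 0.12 ± 0.0283 TPM, and overlapping antisense genes are uncertain here.

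Receptor and channel genes of early postnatal neurons were well represented. Ionotropic glutamate receptor genes had a median of 39.7 ± 2.60 TPM, led by Gria2 (182 ± 13.1), Grin2b (137 ± 25.01), Grik5 (103 ± 2.35) and Grin1 (86.4 ± 7.30), with Grik4 at 6.63 ± 0.0778. GABA-A receptor genes had a median of 28.4 ± 0.354 TPM, with Gabrb2 at 62.0 ± 4.98, Gabra5 at 49.2 ± 1.77 and Gabrd at 4.28 ± 0.912. Sodium channel genes had a median of 45.3 ± 2.97 TPM, led by Scn2a (111 ± 3.60), Scn3b (87.4 ± 0.948), Scn8a (52.6 ± 5.74) and Scn3a (45.3 ± 2.97), with Scn2b at 7.72 ± 1.71.

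Some imprinted genes and some long noncoding genes were abundant. The imprinted genes Meg3 (1109 ± 21.3 TPM), Rian (810 ± 65.6), Nnat (685 ± 39.4) and Snrpn (244 ± 2.99) led a list with a median of 32.6 ± 7.77 TPM, and Dlk1 was lowest at 1.68 ± 0.523. In the other quantification the median of this list was 70.6 TPM and lay in the top 0.5% of random lists. Malat1 stood at 2740 ± 56.2 TPM, Miat at 174 ± 10.8, Snhg11 at 138 ± 1.44 and Neat1 at 4.45 ± 0.792, in a list with a median of 19.8 ± 1.14. Immediate early genes, which respond to activity, had a median of 6.24 ± 0.7495 TPM, with Fosl2 at 20.9 ± 3.10, Jun at 17.8 ± 0.0707 and Egr2 at 1.13 ± 0.0849. Of the 9 interferon response genes 2 were detected, among them Bst2 (1.68 ± 0.276). The chaperones Hspa8 (982 ± 82.3) and Hsp90aa1 (452 ± 8.63) led the heat shock list, whose median was 18.4 ± 0.622 TPM over 7 of 9 members and 7.66 TPM over all 9. Ribosomal protein genes had a median of 331 ± 3.14 TPM and histone genes 42.9 ± 2.96, both in the top 0.5% of random lists. The 15 detected mitochondrially encoded genes, of 37, had a median of 1498 ± 134 TPM and were there as well, but the median over all 37 was 0 TPM and was not. The small structural RNA list, with Rmrp at 3402 ± 109, Rny1 at 87.4 ± 10.6 and Terc at 8.94 ± 2.22 TPM, was there too, but not in the other quantification. Rny1 is 112 bases long and had 21 and 20 reads, so its TPM rests on few reads over a short length. The value of Rmrp is uncertain, because 2 gene identifiers carry this name and each shares at least 96% of its 31-base words with other genes.

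Genes known for early expression exceeded their later counterparts in 10 of 14 pairs, and the later gene was higher in 4. In the other quantification the later gene was higher in 3, and 1 pair was not called. Sst exceeded Pvalb by 8.59 ± 0.17 on the log2 scale (6.75 with a pseudocount of 1), and Pdgfra of oligodendrocyte precursors exceeded Mog of myelin by 7.50 ± 0.42 (4.97 with a pseudocount of 1), with Mog at 1 and 2 reads, so that the sizes of these 2 ratios depend on the pseudocount. Fabp7 exceeded Aqp4 by 3.94 ± 0.12, Nefm exceeded Nefh by 3.82 ± 0.07, Map1b exceeded Map1a by 3.23 ± 0.08 and Tubb3 exceeded Tubb4a by 2.91 ± 0.10. The NMDA receptor subunit Grin2b exceeded Grin2a by 2.42 ± 0.23, Dcx exceeded Rbfox3 by 1.91 ± 0.11, Scn3a exceeded Scn1a by 1.56 ± 0.14 and Ezh2 exceeded Ezh1 by 0.93 ± 0.01. In the other direction, the log2 ratio of Slc17a6 over Slc17a7 was −2.69 ± 0.14, that of Dlg3 over Dlg4 −2.51 ± 0.09 and that of the chloride transporters Slc12a2 over Slc12a5 −2.36 ± 0.07. These ratios are within each library, and no p-value was computed across the 2 animals.

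**Figure D2:**
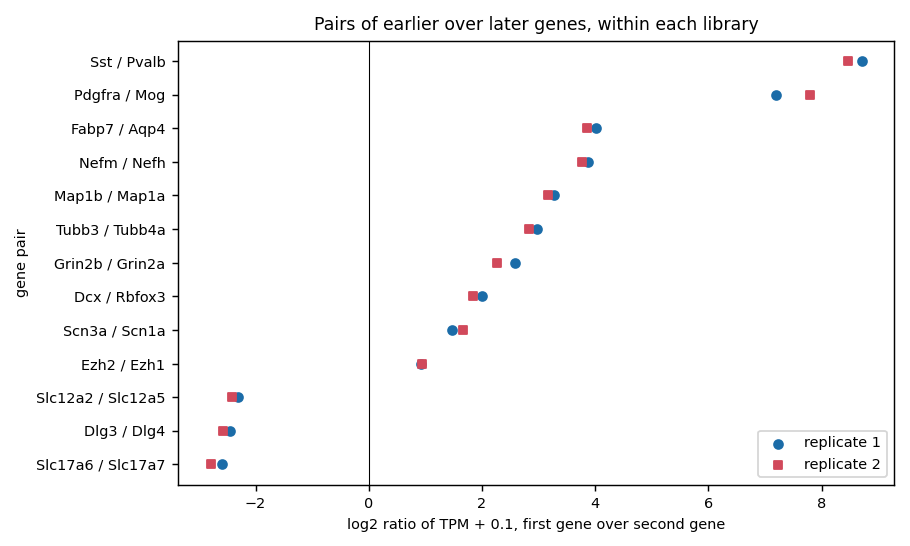
Log2 ratio of TPM + 0.1 of the earlier over the later gene of each of 13 pairs, with 1 point per library. The ratio is above 0 in both libraries for 10 pairs, from Ezh2 over Ezh1 (0.93) to Sst over Pvalb (8.59), and below 0 for 3.

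Gene levels of the 2 animals were close. Across 17047 genes, log2(TPM + 1) correlated with a Pearson r of 0.981 and a Spearman rho of 0.981, where genes are not independent replicates. The log2 ratio of replicate 2 over replicate 1 had an SD of 0.35 over 17993 genes, and 97.9% of these genes were within 2-fold. The biological coefficient of variation was 0.109, or 0.171 as the median of DESeq2's dispersion trend. The spike-ins with at least 10 reads in each library (37 RNAs) had a median log2 ratio of 0.09. The libraries differed by more than sampling noise (chi-square of 171431 on 20364 degrees of freedom). They were counted as 2 samples because the labels list separate tissue samples.

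Ttr, Cdhr1, Lgr5 and Eomes were among the genes that differed most between the libraries. Ttr, the thyroid hormone carrier made in the choroid plexus, was higher in replicate 2, at 32.43 TPM against 1.03 TPM in replicate 1, a log2 ratio of 5.02 (SE 0.331, adjusted p = 7.29e-160, two-sided exact binomial test with Benjamini-Hochberg adjustment). Ttr lies at 18:20665280–20674321. Cdhr1, a cadherin known from photoreceptors and from output neurons of the olfactory bulb (14:37077857–37098347), was at 5.73 and 29.31 TPM, a log2 ratio of 2.43 (SE 0.0768). Eomes, a transcription factor of intermediate progenitors and bulb output neurons (9:118478212–118486132), was at 1.62 and 6.19 TPM, a log2 ratio of 1.92 (SE 0.167). The stem cell receptor Lgr5 had a log2 ratio of 2.09, Pcp4l1 of 1.84, the opioid peptide gene Penk of 1.58, the NMDA receptor subunit Grin2c of 1.53 and Gm49358 of 1.42. All of these passed the same test, but Gm49358 had counts that were not whole (64.81 and 187.99), so it may share reads with other genes.

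Genes lower in replicate 2 included Pla2g4b, a phospholipase, at 4.07 and 1.00 TPM (log2 ratio −1.95, SE 0.231), and the zinc finger gene Zbtb40 (4:136979732–137048801) at 6.35 and 2.51 TPM (log2 ratio −1.51, SE 0.114). The TEC class, gene models that await experimental evidence, gave Gm38029 (−1.48), 6330415B21Rik (−1.39), 2610011E03Rik (−1.26) and Gm9911 (−1.24). Gm14399 had a log2 ratio of −1.35, with counts of 174.65 and 73.55 that were not whole, so it may share reads with other genes. Genes that can share reads are uncertain. Others were Gm24497 (4.18) and 1700047I17Rik2 (2.28), higher in replicate 2, and Gm6361 (−3.17), all without reads in the other quantification. Tmem254b (−1.27) was at −0.26 there, with an adjusted p of 0.147 in the exact binomial test (Benjamini-Hochberg), and the Myl12b model ENSMUSG00000117098.1 (−1.29) turned to 3.12.

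The test called 5313 of 20365 genes, 2784 higher and 2529 lower in replicate 2, so 52.4% were higher. With total count scaling 42.0% of the called genes were higher. Of the called genes, 450 also differed by 2-fold or more, 160 higher and 290 lower, and 172 of the 450 were protein coding. With protein-coding genes tested alone the balance was the other way, with 105 higher and 68 lower by 2-fold or more. The test compares these 2 libraries, not conditions.

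**Figure D3:**
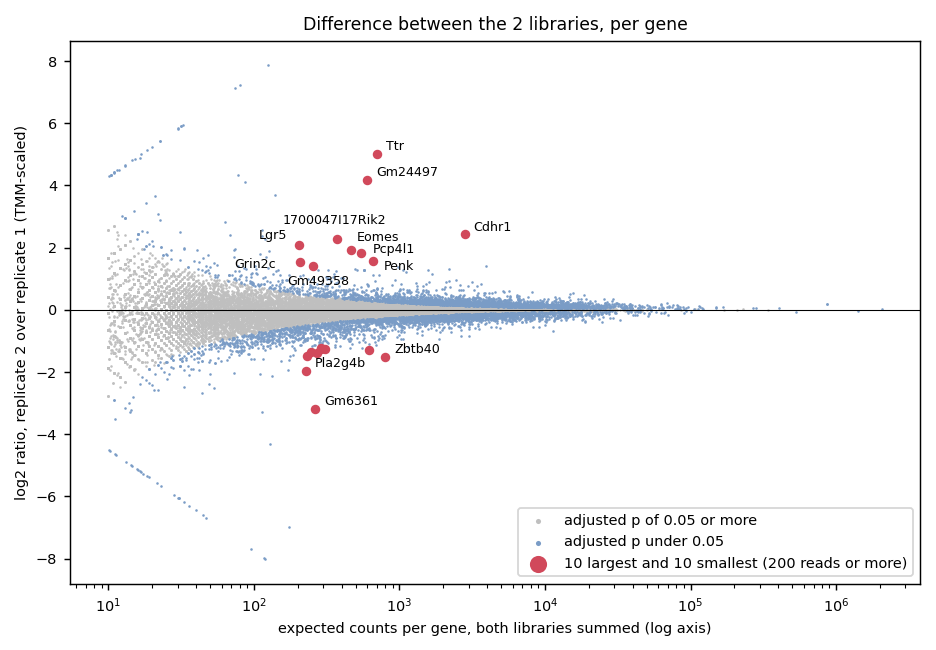
Log2 ratio of replicate 2 over replicate 1 (TMM-scaled) against the summed expected counts (log axis) of each tested gene, with the 20 genes of the largest and smallest ratios in red. Ttr lies at 5.02 and Gm6361 at −3.17.

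Red blood cell, striatal and interneuron genes were higher in replicate 2 as groups. Of 36 lists, 7 lay outside the central 99% of matched random lists, all toward replicate 2. If genes varied independently, 0.36 lists would lie there. Genes of a list can vary together between 2 animals and some lists share genes, so 0.36 is not a chance rate for these lists. Among red blood cell genes the median log2 ratio was 1.05 (scaled median absolute deviation 0.32), and 5 of 6 were higher, with 5 also adjusted over the list alone. Hbb-bs was higher by 1.30 and Hba-a1 by 0.95 on the log2 scale, though the globin genes can share reads. Of 12 striatal genes 11 were higher (11 adjusted over the list alone), with a median of 0.73 (0.41). Ppp1r1b was higher by 0.94, the receptors Adora2a by 0.84 and Drd2 by 0.78, and Drd1 by 0.30. Of 15 interneuron genes 11 were higher (13 adjusted over the list alone), with a median of 0.61 (0.35). Calb2 was higher by 1.29, the transcription factor Dlx1 by 0.84, Gad2 by 0.77 and Gad1 by 0.61, while Sst and Npy were higher by 0.25 each. Lhx6 (0.14), Erbb4 (0.06) and Vip (−0.18) did not pass the test.

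Smaller shifts were seen in the other 4 lists. Astrocyte genes had a median of 0.20 (0.09), with 11 of 14 higher and 1 lower (13 adjusted over the list alone). Aldh1l1 was higher by 0.48, Slc4a4 by 0.34 and Apoe by 0.28, and the gap junction gene Gja1 was lower (−0.14). The Cajal-Retzius median was 0.35 (0.25), with 3 of 8 higher (3 adjusted over the list alone), among them Reln (0.35) and Calb2, which is also in the interneuron list. Trp73, another member, was at −0.04 and did not pass. The myelinating oligodendrocyte median was 0.31 (0.45), with 2 of 10 higher and 1 lower (5 adjusted over the list alone). Cnp was higher by 0.37, Cldn11 was lower (−0.53), and Mbp (−0.09) did not pass. Of 73 ribosomal protein genes 40 were higher and 1 lower (44 adjusted over the list alone), with a median of 0.09 (0.07), and with total count scaling 25 were higher and 1 lower. All 7 medians were above 0 with total count scaling, from 0.07 to 1.02.

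Excitatory neuron and layer genes went both ways. Of 12 excitatory neuron genes 5 were higher in replicate 2 and 3 lower (8 adjusted over the list alone), with Slc17a7 at 0.32 and Camk2a at 0.39 but Bhlhe22 at −0.37 and Neurod6 at −0.27. Deep layer genes had 5 higher and 4 lower of 13 (10 adjusted over the list alone), from Syt6 at 0.74 to Crym at −0.46. With total count scaling, which lowers all log2 ratios alike, 4 were higher and 4 lower in the excitatory list, and 4 higher and 5 lower in the deep layer list. Of 10 upper layer genes 3 were higher and 5 lower (8 adjusted over the list alone), from Cux1 at 0.14 to Pou3f2 at −0.30. Their median of −0.10 (0.22) lay within the central 99% of matched random lists, but below it in the other quantification (−0.06). Of 14 immediate early genes 4 were lower, among them Fos (−1.02) and Egr1 (−0.58), with 4 also adjusted over the list alone. No gene of the microglia list passed, with 14 tested.

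**Figure D4:**
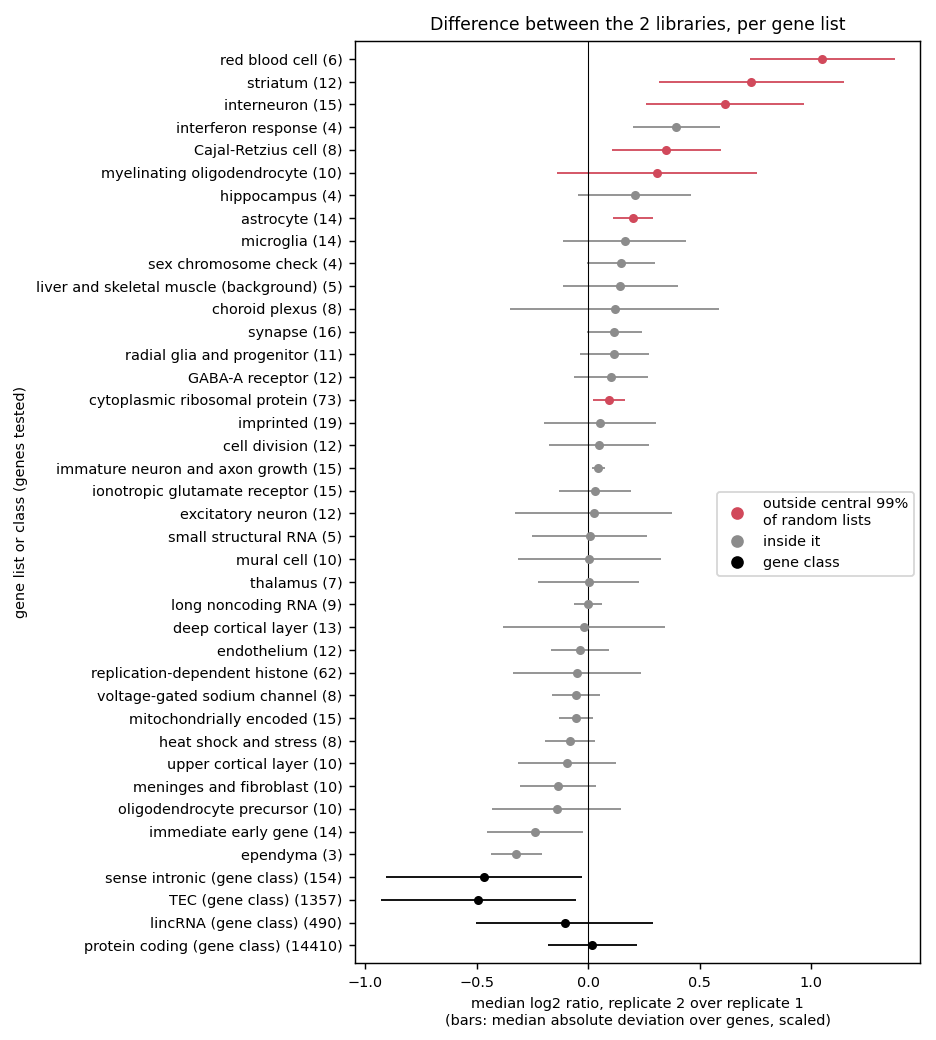
Median log2 ratio of replicate 2 over replicate 1 for each gene list and for 4 gene classes, with bars for the scaled median absolute deviation over genes and the number of genes tested in parentheses. Lists outside the central 99% of matched random lists (red) run from ribosomal protein genes (0.09) to red blood cell genes (1.05), and the TEC class lies at −0.49.

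Gene classes also differed. Genes of the TEC class had a median log2 ratio of −0.49 (scaled median absolute deviation 0.44) over 1357 genes, with 409 lower and 7 higher in replicate 2 by the same test. Sense intronic genes, which lie in introns of other genes, had a median of −0.47 (0.44) over 154 genes, with 32 lower and 3 higher. Protein-coding genes had a median of 0.02 (0.20) over 14410 genes. Of the 1511 genes of both classes, 1201 lie inside an expressed protein-coding gene on the same strand, so that their counts are uncertain. The 283 outside expressed genes had a median of −0.24 (0.49), with 49 lower and 4 higher, and the 27 inside an expressed gene on the opposite strand only had a median of 0.08 (0.25), with 2 lower and 0 higher.

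Splice forms of synaptic and cytoskeletal genes were read from transcript levels. Of the pair Snap25-201 and Snap25-202, which carry different 118-base exons (2:136770057–136770174 and 2:136769743–136769860) and also differ at their ends, the first took 59.2 ± 0.948%. Gria2-202 took 78.6 ± 0.0993% against Gria2-201, with 115-base exons at 3:80690404–80690518 and 3:80691320–80691434 among their differences. Grin1-201, which holds a 111-base exon (2:25294438–25294548), took 73.7 ± 4.17% against Grin1-202. Clta-204 took 75.1 ± 8.44% against Clta-205, which has a 36-base exon (4:44031400–44031435). Cltb-201, with a 54-base exon (13:54597026–54597079), took 73.9 ± 0.150% against Cltb-202. These Cltb transcripts also differ at their ends, so their shares do not measure the 54-base exon alone. In the other quantification these shares ranged from 57.2% for Snap25-201 to 80.0% for Gria2-202.

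**Figure D5:**
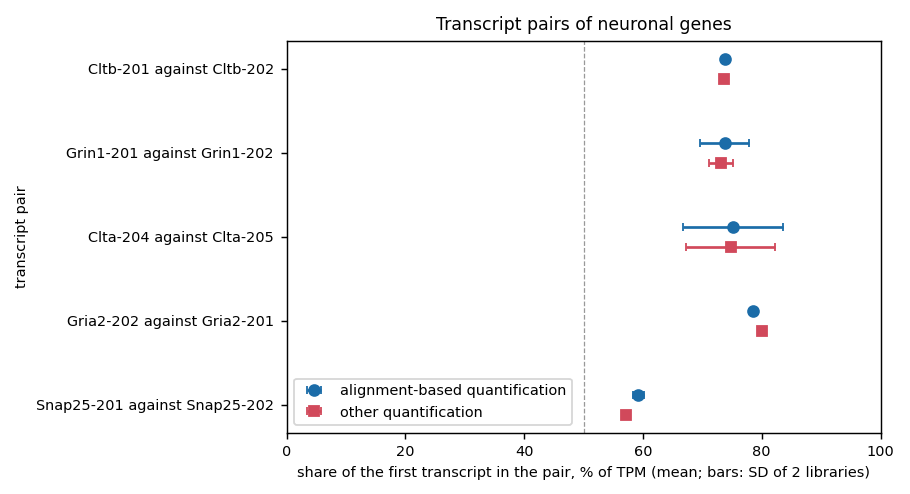
Share of the first transcript of each of 5 pairs, in percent of the pair's TPM, as mean with SD over 2 libraries in each quantification. The first transcript was chosen as the gene's highest, so in the alignment-based quantification its share lies above the dashed line at 50% by construction. There the shares run from 59.2% for Snap25-201 to 78.6% for Gria2-202. In the other quantification they run from 57.2% to 80.0%.

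Single transcripts of other genes depended more on the quantification. Mapt-204 took 92.98 ± 0.223% of the microtubule gene Mapt, and 72.5% in the other quantification. Of the 5 Mapt models with long coding sequence, all 5 hold the 93-base exon at 11:104318157–104318249, so that its skipping was not measured. Map2-204 took 33.1 ± 1.78% and Map2-201 32.0 ± 1.15% of Map2, but Map2-201 took 0.000303% in the other quantification. Dlg4-203 took 46.4 ± 0.422% of Dlg4 and 24.8% there, and Ptbp2-201 took 43.1 ± 1.963% of Ptbp2 and 14.0% there. Of the genes outside the pairs, shares were closer for Bin1-201 (63.0 ± 4.15% and 51.8%), Mbp-205 (48.4 ± 7.41% and 46.6%) and Nrcam-201 (19.2 ± 0.882% and 19.8%).

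The 2 quantifications matched better for protein-coding genes than for transcripts. Across transcripts, log2(TPM + 1) correlated with an r of 0.586 in replicate 1 (60828 transcripts) and 0.593 in replicate 2 (59042 transcripts). Summed over protein-coding genes, r was 0.964 and 0.968. With a pseudocount of 0.1, the mean transcript r was 0.365. The highest transcript of a gene was the same in both quantifications for 75.7% of 9796 genes in replicate 1 (Wilson 95% interval 74.8% to 76.5%), and the same in both libraries for 90.4% (89.8% to 91.0%) in the alignment-based quantification.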

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

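Tests on reads shared between genes that have reads in the other quantification, on the choroid plexus, on the density of genomic DNA reads and on short RNAs were chosen only after the result was seen. Rows with a numeric identifier, which stay outside every comparison, held 6 reads in replicate 1, above the limit of 3 counts that a count of 0 allows. They were looked at because they are data outside the comparisons.

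Of the 10 genes highest in replicate 2 over replicate 1, 8 have reads in the other quantification. All 8 keep an absolute log2 ratio of 1 or more there, the result set to argue against shared reads. Both quantifications divide shared reads by estimate, so a kept ratio cannot decide alone. Counts of Ttr, Cdhr1, Eomes, Pcp4l1, Penk and Grin2c were whole numbers in both, which argues against divided reads for these genes. Those of Gm49358 were not, and its TPM intervals overlapped (0.215 to 5.62 in replicate 1, 5.33 to 10.98 in replicate 2). Those of Lgr5 were not whole in the other quantification. For Gm24497 and 1700047I17Rik2, which have no reads there, at least 96.3% of their 31-base words occur in other genes, so shared reads may account for both. A larger share of olfactory bulb tissue stays open as a candidate source. Before the test, 12 bulb markers were listed. This cortex expresses 7 of them at a TPM of 1 in replicate 1, and 0 are in other lists. Over the 9 tested, the median log2 ratio was 0.51 (scaled median absolute deviation 0.43), with 5 higher by the binomial test and 0 lower. That median was above the bound of 0.5 set beforehand and at the 99.99th percentile of matched random lists. Genes of a list can vary together, so this percentile is not a chance rate. In the other quantification the median was 0.39, under that bound. The striatum list, which holds Penk, was higher too (median log2 ratio 0.73, or 0.68 without Penk; 11 of 12 higher), and no test separated the 2 lists. The most abundant bulb marker, Meis2, was at 92.76 and 116.78 TPM, and Etv1 at 26.23 and 30.23 TPM. Tbx21 (4 and 83 reads), Scgn (3 and 12) and Lbhd2 (7 and 24) had under 10 counts in replicate 1. They were therefore not among the 9 tested. Choroid plexus tissue as a source of Ttr cannot be told apart from other sources, since the other 7 choroid genes had a median log2 ratio of 0.10 and 3 of them had 50 reads in each library, and no biological explanation was tested because there is 1 group.

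Genes of the TEC class, gene models that await experimental evidence, and sense intronic genes were lower in replicate 2. A GC and length trend fitted on protein-coding genes left 90.6% of their median log2 ratio. Protein-coding genes with symbols that begin with Olfr, Vmn or Tas, mainly receptor genes, held 0.922% of the members' median reads per kilobase in replicate 1. They were picked by symbol and not checked to be silent, and transcripts of any expressed gene among them would add to that share. GC content, length and evenly spread genomic DNA are therefore argued against as the whole cause. The test of genomic DNA set beforehand did not decide, since the genes picked by symbol had a log2 ratio of −0.16 (interval −0.28 to −0.05), between its bounds of −0.3 and −0.1. Transcripts of an expressed gene among them could also shift that ratio. More unspliced RNA in replicate 1 stays open as a candidate explanation: members inside an expressed gene on the same strand were lower by a difference of −0.34 on the log2 scale than the other members (1201 and 310 genes, 27 of the 310 inside an expressed gene on the opposite strand). Transcripts that retain an intron were set against coding transcripts of the same 5845 genes, with no bound set. The median difference in log2 ratio was −0.139 (scaled median absolute deviation 0.42), and 63.0% of genes were lower. No biological explanation was tested.

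Short structural RNAs such as Rn7s1 and Rn7sk are absent from the other quantification. Single-transcript genes shorter than its assumed fragment of 347 and 342 bases kept a median of 0% of their reads (215 genes), while those over 1.5 times as long kept 106%, consistent with a loss of transcripts shorter than the assumed fragment. The 32 short genes that share no 31-base word with another gene kept a median of 0% as well; 9 of them kept some reads, at most 36%. Reads shared between copies predicted that they keep 50% or more, so sharing is argued against as the whole cause. No biological explanation was tested.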

How the results depend on the processing

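The other quantification for the binomial test and for named genes, lists without the named genes, and posterior mean TPM for list levels were chosen after seeing the data. The correlation between libraries was 0.949 with a pseudocount of 0.1, 0.993 with no filter, 0.977 with a TPM of 5 and 0.985 in the other quantification. With 100 counts in each library the SD of the log2 ratio was 0.2276, since genes with few counts were left out. The biological coefficient of variation was 0.113 with no filter and 0.171 as DESeq2's trend median. With protein-coding genes tested alone 173 differed by 2-fold, against 172 protein-coding genes among the 450 of the main test. The share of other protein-coding genes was 82.2% of counts, and 51.8% of TPM without spike-in and mitochondrial rows. Between quantifications the transcript r was 0.623 for protein-coding genes and 0.365 with a pseudocount of 0.1, and the highest transcript matched in 74.7% of genes at a TPM of 1 and 74.8% at a TPM of 20. Myl12b reversed to 3.12 in the other quantification. Where no cause is given, the cause was not tested. Of the other values, 30 summary ones stayed within the bounds set for them, 1.5-fold for counts. Among single ones, 319 kept direction and side of the threshold or moved by no more than 1 SD, and 96 moved further. A further 1 (Tmem254b) no longer passed and 1 (the upper layer list, −0.06) passed newly. Some of the 319 could not have come out otherwise. With 2 libraries, a pair ratio from 1 library always lies within 1 SD of the mean. Other scalings shift the log2 ratios of the 20 named genes by a constant much smaller than these ratios, and only direction was checked there. Genes detected numbered 21621 at a TPM of 0.1 and 11161 at a TPM of 5. Without 1 library, 16060 to 16564 genes were detected and 8 to 9 lists were in the top 0.5% in level. The 10 pairs stayed above 0, which a call with the same sign in both libraries already requires. Gm24497, 1700047I17Rik2 and Gm6361 have no reads in the other quantification and give no value there. No paired analysis was possible because there is 1 group. Depth limits genes under 3 counts, or 0.112 and 0.102 CPM.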

Other observations

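Families looked at here were chosen after their values were seen, and no test was run on them. The tubulins, the subunits of microtubules, summed to 11517 ± 132 TPM (SD, n = 2), with 13 of 17 genes detected. Beyond Tuba1a and Tubb2b, Tubb2a stood at 1380 TPM and Tubb5 at 1280 TPM. The synaptic adhesion genes of the neurexin, neuroligin and latrophilin families were all detected (9 of 9) and summed to 1451 ± 9.21 TPM, with Nrxn2 at 361 TPM. Of the clustered protocadherins, adhesion molecules that give neurons distinct surfaces, 14 of 14 alpha genes (148 ± 0.205 TPM in sum), 21 of 22 beta genes (89.8 ± 3.92) and 21 of 21 gamma genes (290.5 ± 8.29) were detected, but the members of a cluster share exons or sequence and their split is uncertain. Pcdhgc3 led the gamma genes at 69.3 TPM.

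Among 26 genes for neuropeptides and growth factors 22 were detected. The heparin-binding growth factor Ptn stood at 349 TPM and the peptide gene Cck at 89.3 TPM. None of 1135 olfactory receptor genes was detected.

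A pair of protein-coding genes had reads almost only in 1 library, in both quantifications. Tspan10, a tetraspanin, had 174 reads in replicate 1 and 1 in replicate 2, a ratio of 187 with an exact 95% counting interval of 33.1 to 7433. Ms4a15 had 3 reads in replicate 1 and 75 in replicate 2, a ratio of 23.2 with an interval of 7.66 to 115. No explanation was tested for either.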
